A study of Mus musculus with 3 samples.

How the data were processed

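The series holds RNA-seq of mouse intestine from 3 groups with 1 library each. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was assessed, and libraries were sequenced on an Illumina NovaSeq as 150 bp paired-end reads. The authors deposited 1 table of raw read counts per gene symbol for all 3 libraries. The genome build was mm10, per the submitters' processing notes. The aligner, the annotation, the strand setting and any filter are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, may share counts. Genes such as Gapdh (5.16 CPM) and Rpl13a (9.06 CPM) were counted low in the control library. They were at 33.3 and 15.4 CPM in the NEC and at 3.55 and 7.82 CPM in the PCI34051+NEC library. Levels of genes with near-identical copies, the mitochondrially encoded ones among them, may therefore be understated. The extent of this may differ between libraries. The control and NEC columns were matched to samples by name. The name of the third column did not match the description of the PCI34051+NEC sample letter for letter, and it was assigned because no other column named an inhibitor; every PCI34051+NEC value rests on that. No column was left unused, and the table held no row of unassigned reads. The labels do not say whether a library is 1 pup or a pool.

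The table listed 21983 genes, of which 21926 symbols matched GENCODE release M21 on the same build, 99.4% of the table being protein-coding. Gene identifiers and coordinates were taken from that annotation. Totals were 15076413, 10650638 and 16497580 counts for control, NEC and PCI34051+NEC, so 3 counts, the floor used for a count of 0, corresponded to 0.189, 0.274 and 0.197 CPM. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

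Counts were scaled with TMM in edgeR 4.0.16 (R 4.3.3) over all 3 libraries, with factors of 1.05, 1.03 and 0.923. Log2 folds were taken on CPM plus a pseudocount of 1, which understates the difference of low genes. Fold ratios printed with an interval are plain ratios of CPM with exact conditional binomial (Clopper-Pearson) intervals. A gene was measured in a comparison with at least 1 CPM in 1 or more of its libraries, and was counted as higher or lower at a 2-fold difference. With 1 library per group no replicated test, standard error or p-value could be given. A list's median is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

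The groups, the size thresholds, 62 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Hdac8, the 12 genes with the largest difference each way per comparison at 10 CPM or more in the higher library (predicted genes and small RNAs left out), the 8 genes each way that set the NEC library apart most, up to 4 members of each list described with the largest difference at 5 CPM or more, and any member of the arginine and proline list. The text prints those of these genes that it describes. Apoa4, Cdh1 and Vil1 and the genes and lists drawn in the plots were chosen after their values were seen. Lists with under 4 measured members have values only. Some genes stand in more than 1 list, as Fabp1 does.

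The procedure was tested on counts simulated with Poisson counting error alone for the NEC and control libraries over 21983 genes, with 50 genes at each of 4 known log2 folds. The intervals assume that error, so their coverage was largely fixed in advance. Few genes were changed, all at 10 CPM or more and as many up as down. Scaling with 47.1% of genes 2-fold apart, as in these data, was therefore not tested. Folds of -2, -1, 1 and 2 came out at medians of -1.91, -0.98, 0.98 and 1.97, and the counting intervals covered the true value in 92%, 90%, 100% and 96% of genes. Unchanged libraries were also simulated, with coefficients of variation of 0.2 and 0.4 between libraries, which are assumed and not measured values. Alternatives were DESeq2 1.42.0 size factors, total counts, scaling without the 50 most abundant and the mitochondrially encoded genes, pseudocounts of 0.25 and 4, no filter, a minimum of 5 CPM, thinning to 10650638 counts, a 1.5-fold threshold, and counting intervals beyond 2-fold. Removal of the trend with GC content and transcript length (30 bins each, values for 99.8% of genes) and TMM without the NEC library were added after the data were seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.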

Results

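RNA was sequenced from the intestine of mouse pups in 3 groups, with 1 library per group. The control library came from dam-fed pups. The NEC library came from a model of necrotizing enterocolitis (NEC), an inflammatory bowel disease of the newborn, in which pups were gavaged with 40 µl of 33% formula every 4 h for 96 h. At intervals of 12 h these pups also went through hypoxia (99.9% nitrogen, 100 s) and then cold (10 min at 4 °C). The PCI34051+NEC library came from pups put through the same model and fed PCI34051 at 10 mg/kg per day for 5 days, where the pups of the remaining groups received PBS. PCI34051 is an inhibitor selective for HDAC8, a zinc-dependent lysine deacetylase. The libraries held 15076413 (control), 10650638 (NEC) and 16497580 (PCI34051+NEC) counts over 21983 genes. There were no replicates, so no difference below has a replicate check, no p-value is given, and every value describes these 3 libraries and not the conditions. Intervals are 95% intervals and cover counting error only. Levels are TMM-normalised read counts (CPM), and log2 folds are on the log2(CPM + 1) scale.

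The comparison of NEC with control addressed which genes differ between the intestine of the model and that of dam-fed pups. Hdac8 and arginine-proline metabolism are named by the study's title. Feeding, hypoxia and cold differed together with any disease in this comparison, so their parts could not be told apart. Hdac8 (ENSMUSG00000067567, chromosome X, 102284639 to 102505359, minus strand, mm10, protein-coding) was at 6.48 CPM in the control library (103 counts) and 11.96 CPM in the NEC library (131 counts). That was 1.85-fold higher (1.42 to 2.41), or 0.79 on the log2 scale. Among all measured genes this was not a large difference: 47.1% were at least 2-fold apart, and log2 folds had a standard deviation of 1.36. Of the 11 histone deacetylase genes, only Hdac9 (4.28 CPM) was lower than Hdac8 in the control library. Hdac7 was 6.44-fold higher (5.69 to 7.32), at 19.2 and 124 CPM. Hdac6, a cytoplasmic tubulin deacetylase, was at 25.6 and 72.1 CPM, whereas Hdac11 was lower, at 21.02 and 8.13 CPM. The median log2 fold of the 11 genes was 0.79, at percentile 97.6 of random lists matched on expression, with 4 genes at least 2-fold higher and 1 lower. With the trend with GC content and transcript length removed, an alternative added after the data were seen, this median was 0.18 and that of Hdac8 alone 1.11.

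Genes of arginine and proline metabolism were mostly lower in the NEC library. Of 49 measured genes, 21 were at least 2-fold lower and 7 at least 2-fold higher, with a median log2 fold of -0.85 at percentile 0.66 of random lists. The median was -0.66 with the GC content and length trend removed and -0.67 with a pseudocount of 4. Both lie inside the random range of -0.74 to 0.22, which was made without these changes, so neither has a percentile. The genes that make citrulline and arginine from glutamine and proline stood lowest. Of 11 measured genes of the urea cycle and citrulline synthesis, 9 were at least 2-fold lower and 1 (Arg1, at 0.566 and 3.11 CPM) was higher, with a median of -2.03 at percentile 0.03. Cps1, the mitochondrial carbamoyl phosphate synthetase (chromosome 1, 67123026 to 67231259, plus strand), was at 715 CPM in the control and 118 CPM in the NEC library, 6.06-fold lower (5.72 to 6.42). Ass1, argininosuccinate synthase (chromosome 2, 31470207 to 31520672, plus strand), was 6.81-fold lower (6.14 to 7.58), at 241 and 35.4 CPM. Oat, ornithine aminotransferase (chromosome 7, 132557478 to 132576398, minus strand), was 5.19-fold lower (5.03 to 5.36), at 2011 and 387 CPM. Aldh18a1, which makes the precursor shared by proline and ornithine, was at 653 and 141 CPM.

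Of 15 measured arginine and proline transporter genes, 8 were at least 2-fold lower and 4 at least 2-fold higher in the NEC library, with a median of -1.15 at percentile 1.55. Slc7a9 and Slc3a1, the subunits of the apical cationic amino acid transporter, were at 549 and 103 CPM and at 132 and 25.8 CPM. Slc6a14 had 493 counts in the control and 0 in the NEC library, at least 113-fold lower against a floor of 3 counts. Polyamine genes went both ways, with 3 of 14 at least 2-fold higher, 5 lower and a median of 0.06. Odc1, the rate-limiting enzyme of polyamine synthesis, was 7.44-fold lower (6.34 to 8.78). Some members of the arginine and proline list were higher, among them endothelial nitric oxide synthase Nos3 (5.03 and 35.9 CPM) and the brain-type creatine kinase Ckb (157 and 357 CPM).

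**Figure D1:**
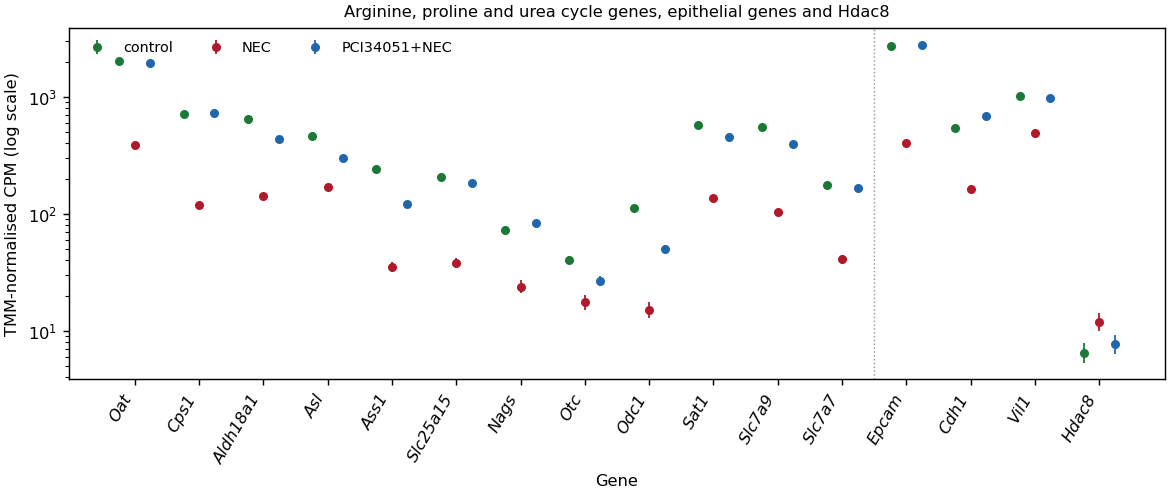
Levels of arginine, proline and urea cycle genes, 3 epithelial genes and Hdac8 (genes on the horizontal axis, chosen after their values were seen; CPM on a log scale on the vertical axis). Each point is 1 library and each bar its 95% Poisson counting interval; the NEC points lie below both others for each gene except Hdac8, as for Cps1 at 118 CPM against 715 in the control and 728 in the PCI34051+NEC library.

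Junction and suckling-type enterocyte genes were lower alongside them, while other epithelial lists were within the random range or higher. Of 18 tight and adherens junction genes, 10 were at least 2-fold lower and 2 higher, with a median of -1.38 at percentile 1.03. Epcam, an epithelial adhesion molecule, was 6.75-fold lower (6.55 to 6.97), at 2731 and 404 CPM, and Cldn8 was at 126 and 9.68 CPM. Of 13 genes of the suckling-type enterocyte, which takes up milk macromolecules by endocytosis, 12 were at least 2-fold lower and none 2-fold higher, with a median of -2.64 and no random list as low. The lysosomal protease Ctsl was 21.8-fold lower (20.8 to 22.8). Absorptive enterocyte genes had a median of -1.04, with 13 of 23 at least 2-fold lower, but at percentile 28.3 they were within the random range. Tuft cell genes, with 4 of 10 measured, had a median of 1.49 at percentile 98.4. With genes at 0 counts set at the floor it was 1.37. The random range, which ended at 1.415, was made without that floor, so 1.37 has no percentile. Genes of stem cells and crypt base (0.47) and of regenerating or fetal epithelium (0.99) were within the random range. Fabp1, a fatty acid binding protein, was an exception, with 2 counts in the control and 743 in the NEC library, a ratio of 539 (149 to 4460).

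Genes of the muscle wall and connective tissue were higher in the NEC library. Of 12 smooth muscle genes, 8 were at least 2-fold higher and 1 lower, with a median of 1.498 at percentile 99.99. Myh11, the smooth muscle myosin heavy chain, was 15.7-fold higher (15.2 to 16.2), at 268 and 4215 CPM. Enteric neuron and glia genes had a median of 2.05 at percentile 99.99, with 9 of 12 at least 2-fold higher, such as Uchl1 at 17.8 and 138 CPM. Fibroblast and matrix genes had a median of 1.82, with 9 of 13 at least 2-fold higher, and Col1a1 was at 142 and 666 CPM. All 11 measured Paneth cell genes were at least 2-fold higher, with a median of 2.78, among them Lyz1 with 8 counts in the control and 184 in the NEC library. The alpha-defensins among them are near-identical copies whose counts are uncertain.

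The mitochondrially encoded genes took 32.4% of counts in the NEC library (32.41 to 32.47, Wilson interval), against 4.88% in the control and 3.73% in the PCI34051+NEC library. The most abundant gene of the NEC library, mt-Co1, alone took 16.0%. The mitochondrial share covers only what the authors' counting assigned, since mt-Co2, mt-Co3 and mt-Atp6 had only 159, 202 and 85 counts in the control library. Of 18 nuclear genes of oxidative phosphorylation, 7 were at least 2-fold lower and 1 higher in the NEC library, with a median of -0.79 at percentile 26.5, within the range of random lists. Counts of the Y-linked genes were near 0 in the NEC library alone. Eif2s3y had 999 counts in the control, 0 in the NEC and 1134 in the PCI34051+NEC library, so that it was at least 229-fold lower in the NEC library than in the control. The labels do not give the sex of the pups. Hdac8 lies on chromosome X, and its folds in comparisons with the NEC library could not be separated from a difference in sex.

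**Figure D2:**
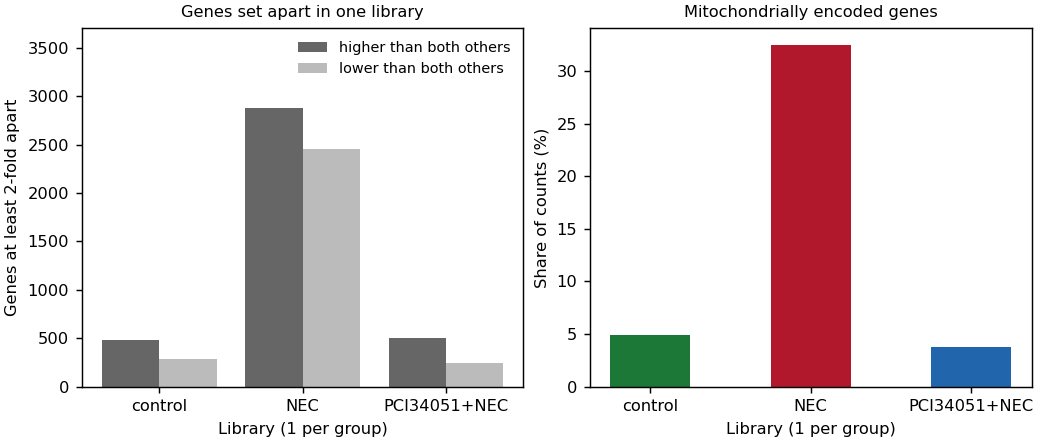
Left, genes at least 2-fold higher or lower in 1 library than in both others (number of genes); right, share of counts from mitochondrially encoded genes (%). The NEC library was set apart in 2875 genes higher and 2456 lower, and its mitochondrial share was 32.4%.

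Interferon-response and antigen presentation genes were lower in the NEC library, and glucocorticoid target genes were higher. Of 31 interferon-response genes, 22 were at least 2-fold lower and none 2-fold higher, with a median of -1.78 and no random list as low. Ifit1 was 69.5-fold lower (52.6 to 93.8), at 317 and 4.57 CPM, and Isg15 was 90.9-fold lower (38.8 to 281). Of 7 MHC class II genes, 6 were at least 2-fold lower, with a median of -3.68, and H2-Ab1 was at 62.6 and 3.01 CPM. B cell genes had a median of -2.23, or -2.06 with genes at 0 counts set at the floor. T cell genes had a median of -1.74, or -1.39 with such genes at the floor. Of 10 glucocorticoid targets, 6 were at least 2-fold higher and none 2-fold lower, with a median of 1.80 at percentile 99.99. Fkbp5, a co-chaperone of the glucocorticoid receptor, was 54.7-fold higher (44.1 to 68.6), at 5.35 and 292 CPM. Of 17 inflammatory cytokine and chemokine genes, 5 were at least 2-fold higher and 3 lower, with a median of 0.24 at percentile 24.0. Antimicrobial and acute phase genes had a median of 0.68 at percentile 75.8, with 6 of 16 at least 2-fold higher and 2 lower. Among them, Lcn2 had 3 counts in the control and 133 in the NEC library, a ratio of 64.3 (21.5 to 316), Saa3 had 5 and 199 counts, and Sprr2a1 was lower, with 146 and 0 counts.

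Across all genes, 3540 of 14627 were at least 2-fold higher and 3354 at least 2-fold lower in the NEC than in the control library, 47.1% in all. The largest differences also included the transporter gene Slc10a6 (0.44 and 92.1 CPM), the kinase gene Map3k6 (2.64 and 191 CPM) and the receptor gene Ager (3.15 and 181 CPM), all higher. Rarres1 (325 and 7.76 CPM), Rtp4 (90.9 and 1.55 CPM) and the fetal serum protein gene Afp (786 and 27.6 CPM) were lower. Simulated unchanged libraries at these depths gave 222 such genes with a coefficient of variation of 0.2 between libraries and 2763 with 0.4.

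The comparison of PCI34051+NEC with NEC addressed what differs with the inhibitor in the model. Hdac8 was at 7.69 CPM (117 counts) in the PCI34051+NEC library, 1.56-fold lower than in the NEC library (1.20 to 2.01). Here 50.6% of all measured genes were at least 2-fold apart, so this was not a large difference among them. The 11 deacetylase genes had a median of -0.98 at percentile 1.09. Arginine and proline genes were mostly higher than in the NEC library, with 23 of 49 at least 2-fold higher, 10 lower and a median of 0.82. Its percentile of 96.9 lay within the central 95% of random lists. Urea cycle and citrulline synthesis genes had a median of 1.74 at percentile 98.5, with 8 of 11 at least 2-fold higher and 1 lower. Cps1 was 6.16-fold higher (5.82 to 6.53), at 728 CPM, and Oat 5.01-fold higher (4.85 to 5.17), at 1939 CPM. The transporter genes had a median of 1.20 at percentile 95.8.

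Junction, absorptive and suckling-type enterocyte genes were higher with PCI34051, and muscle wall and Paneth cell genes were lower. Junction genes had a median of 1.98 at percentile 99.9, with 14 of 18 at least 2-fold higher, and Epcam was 6.92-fold higher (6.70 to 7.13). Absorptive enterocyte genes had a median of 2.16, with 20 of 23 at least 2-fold higher and none 2-fold lower. Mttp, which loads lipid onto lipoproteins, was 6.64-fold higher (6.47 to 6.82). Suckling-type enterocyte genes had a median of 2.29, with 12 of 13 at least 2-fold higher. Smooth muscle genes had a median of -1.84, with 10 of 12 at least 2-fold lower, and Myh11 was 14.7-fold lower (14.3 to 15.2). All 11 Paneth cell genes were at least 2-fold lower, with a median of -2.30, or -2.04 with genes at 0 counts set at the floor. The 4 measured tuft cell genes had a median of -1.56 at percentile 1.20, or -1.44 with such genes at the floor. The random range, from -1.455, was made without that floor, so -1.44 has no percentile. Goblet (-0.37), stem and crypt base (-0.68) and regenerating or fetal epithelium genes (-0.83) were within the random range. Fatty acid oxidation genes had a median of 1.65 at percentile 99.7, with 17 of 23 at least 2-fold higher.

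Among all genes, 3597 of 14410 were at least 2-fold higher and 3695 at least 2-fold lower, 50.6% in all, against 188 and 2651 genes in the simulated unchanged libraries. The largest differences downward included Alb (100.4 and 0.394 CPM, 6 counts with PCI34051), the calcium channel gene Cacna1g (150 and 5.32 CPM), the complement gene C4b (131 and 4.93 CPM) and the tissue factor gene F3 (105 and 4.27 CPM). The liver genes Ahsg (0.944, 11.96 and 0.131 CPM in the control, NEC and PCI34051+NEC libraries) and Fgg (1.76, 11.7 and 0.263 CPM) were, like Alb, highest in the NEC library, whereas Ttr and Afp were lowest there. The 12 liver genes had a median of 0.97 in NEC against control, at percentile 97.4, and of -0.82 at percentile 7.50 in PCI34051+NEC against NEC, both within the random range. Upward, beyond the Y-linked genes, they included Clca4a (2.92 and 62.6 CPM), Ltf (0.457 and 27.6 CPM) and Afp (27.6 and 321 CPM). The NEC library enters this comparison and the one with control, which ties them together. Of the 6894 genes at least 2-fold apart between NEC and control, 86.4% were nearer to the control than to the NEC level in the PCI34051+NEC library. Exchangeable libraries give about 50%, and the simulated ones gave 53.6% and 48.9%. The mirrored share was alike: of genes apart between NEC and PCI34051+NEC, 85% were nearer to the PCI34051+NEC level in the control library. Across genes, which are not independent, the folds of NEC over control and of PCI34051+NEC over NEC had a correlation of -0.864 and a covariance of -1.58, where simulated unchanged libraries at the larger variation gave -0.505 and -0.304.

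**Figure D3:**
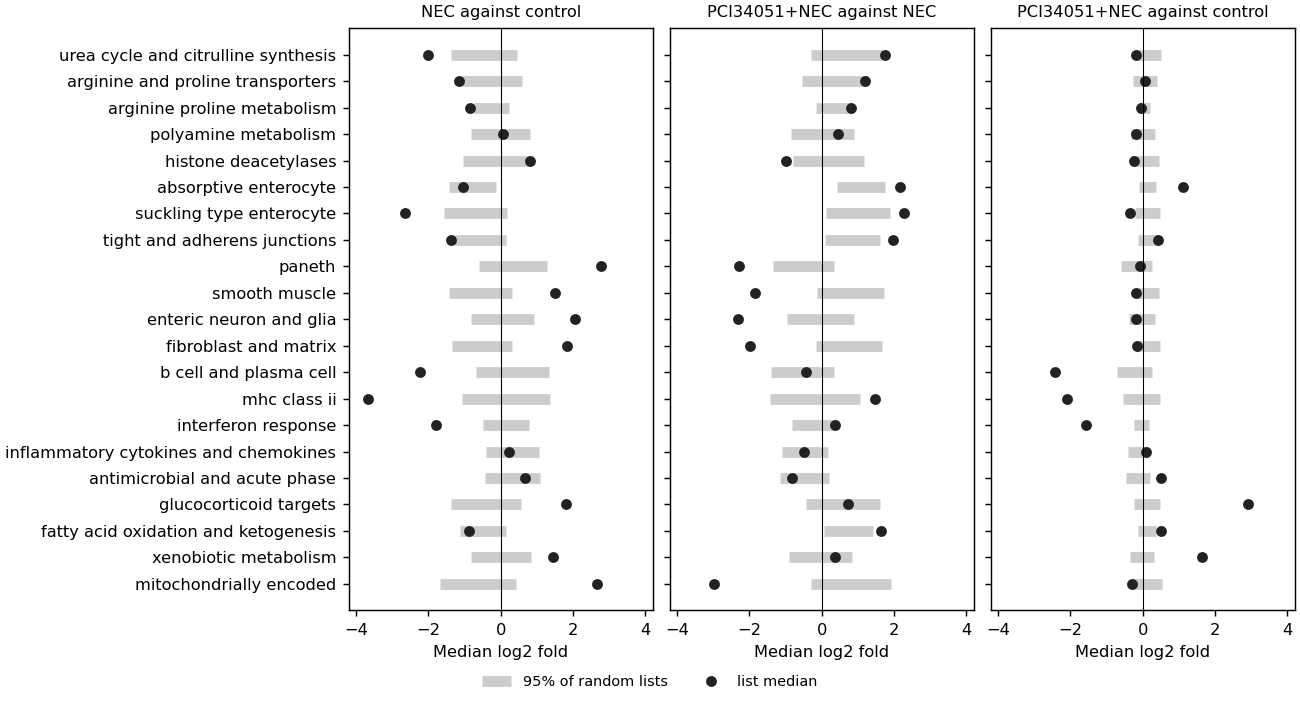
Median log2 fold of 21 gene lists (vertical axis, chosen for display after their values were seen) in the 3 comparisons (panels). Points are list medians and grey bars the central 95% of 10000 random lists matched on expression; interferon-response genes stood at -1.78 and -1.56 against control, and smooth muscle genes at 1.498 in NEC and -0.19 in PCI34051+NEC.

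The comparison of PCI34051+NEC with control showed how far the treated library was from the dam-fed one. The median of arginine and proline genes lay near the control level, at -0.05 (percentile 12.4), while members differed both ways. Of 49 genes, 4 were at least 2-fold higher, such as Hoga1 (28.1 CPM in control and 123 CPM with PCI34051). A further 5 were at least 2-fold lower, such as Aldh7a1 (176 and 66.0 CPM). Of all measured genes, 13.1% were at least 2-fold apart, so these counts did not set the list closer to control than other genes. The urea cycle list had a median of -0.19 at percentile 4.33 and no gene 2-fold apart, and Ass1 was 2.0-fold lower (1.89 to 2.12) before the pseudocount. Odc1 was 2.22-fold lower (2.03 to 2.41). Hdac8 differed by 1.19-fold (0.902 to 1.56), which was within its counting error. Smooth muscle genes had a median of -0.19 and no gene 2-fold apart.

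Glucocorticoid target, absorptive enterocyte and xenobiotic metabolism genes were higher than in control, while fatty acid synthesis genes had a median of -0.05. Of 10 glucocorticoid targets, 7 were at least 2-fold higher and none 2-fold lower, with a median of 2.92 and no random list as high. Fkbp5 was 88.1-fold higher (71.1 to 110), at 471 CPM. Zbtb16 was 46.8-fold higher (27.7 to 86.2), and Pdk4, an inhibitor of pyruvate oxidation, was 18.0-fold higher (15.8 to 20.6). Of 23 absorptive enterocyte genes, 13 were at least 2-fold higher and none 2-fold lower, with a median of 1.10. Fabp1 had 2 counts in the control and 5537 with PCI34051, a ratio of 2890 (800 to 23900). Mttp was 5.88-fold higher (5.76 to 6.01), and Apoa4, a lipoprotein of dietary fat absorption, was at 20142 and 58772 CPM. Of 17 xenobiotic metabolism genes, 11 were at least 2-fold higher and none 2-fold lower, with a median of 1.65, and Ugt1a1 was at 13.8 and 102 CPM. The xenobiotic list was also higher in the NEC library than in control, with a median of 1.44 at percentile 99.9, 10 genes at least 2-fold higher and 2 lower. Between the PCI34051+NEC and NEC libraries it had a median of 0.38 at percentile 81.1. The metal-binding gene Mt2 was 16.1-fold higher (15.3 to 16.9).

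Interferon-response, MHC class II and lymphocyte genes were lower than in control here too. Both comparisons use the same control library, so that library alone could give both results. Of 31 interferon-response genes, 24 were at least 2-fold lower and none 2-fold higher, with a median of -1.56. Isg15 was 39.5-fold lower (24.1 to 69.5) and Oasl2 was at 152 and 10.9 CPM. MHC class II genes had a median of -2.10, with 5 of 7 at least 2-fold lower. All 8 B cell genes were at least 2-fold lower, with a median of -2.41, or -2.28 with genes at 0 counts at the floor. Cd79a, part of the B cell receptor, had 209 counts in the control and 5 with PCI34051. T cell genes had a median of -1.64, or -1.48 with such genes at the floor. Between the PCI34051+NEC and NEC libraries, interferon-response genes had a median of 0.37 at percentile 96.2, within the random range. MHC class II genes had a median of 1.47 at percentile 99.7 there. Against control, enteroendocrine genes had a median of -0.71 at percentile 0.01, although 1 of 14 was 2-fold lower. Suckling-type enterocyte (-0.36, percentile 0.14), goblet (-0.57, 0.72) and proliferation genes (-0.50, 0.39) also lay below the random range. Regenerating or fetal epithelium genes (0.69, 99.9) lay above it. So did antimicrobial and acute phase genes (0.52, 99.99), although 3 of 16 were at least 2-fold higher and 3 lower.

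**Figure D4:**
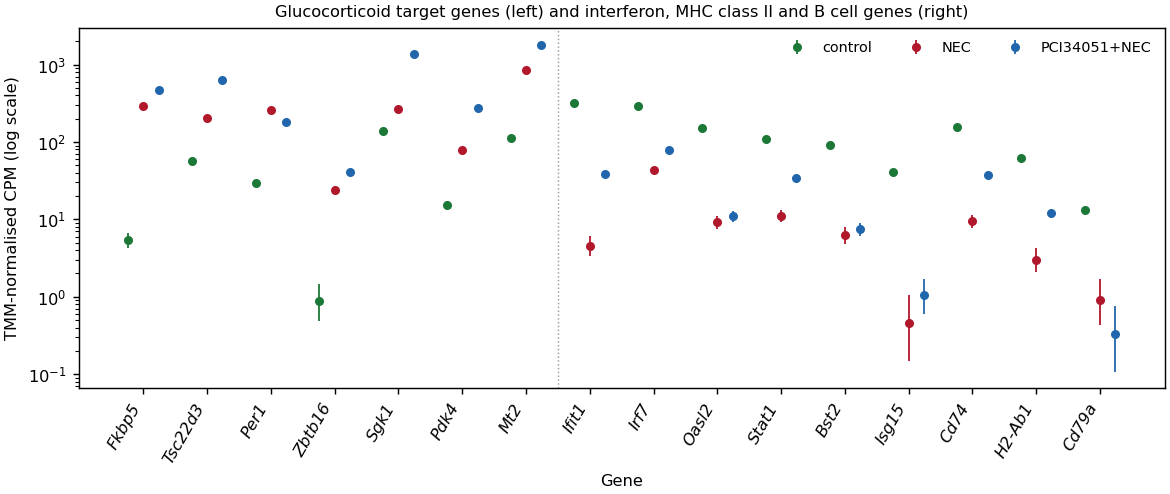
Levels of glucocorticoid target and metallothionein genes (left of the dotted line) and of interferon, MHC class II and B cell genes (right), on a log CPM axis, 1 point per library with its 95% Poisson counting interval. Genes were chosen after their values were seen; Fkbp5 was at 5.35, 292 and 471 CPM and Ifit1 at 317, 4.57 and 38.4 CPM in the control, NEC and PCI34051+NEC libraries.

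In all, 894 of 13652 genes were at least 2-fold higher and 894 at least 2-fold lower in the PCI34051+NEC than in the control library, 13.1%. Simulated unchanged libraries gave 159 such genes at the smaller and 2660 at the larger variation, so these 1788 were fewer than the latter. With scaling to total counts, 33.5% of the genes 2-fold apart were higher, where the TMM scaling gave 50%. Genes at least 2-fold apart from both other libraries numbered 5331 for the NEC library, 769 for the control and 751 for the PCI34051+NEC library, where simulated unchanged libraries gave 910, 906 and 837 at the larger variation. The correlation across genes (Spearman) was 0.947 between PCI34051+NEC and control, 0.799 between NEC and control, and 0.811 between PCI34051+NEC and NEC. The folds of NEC and PCI34051+NEC over the shared control had a correlation of 0.264 and a covariance of 0.253 across genes, where simulated unchanged libraries gave 0.505 and 0.304 at the larger variation.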

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

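The GC content and transcript length correction and the TMM scaling without the NEC library were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Of 160 values of the counts, the Hdac8 folds, the arginine and proline medians and the share nearer control under these alternatives, 136 stayed within their interval or 1.5 times and 24 moved further. The interval of the share was binomial over genes taken as independent, which they are not. No value with a direction beyond counting error or the random range reversed. Of 2385 values of other genes and lists, 676 moved. With total counts the median of all genes moved by -0.15 (PCI34051+NEC against NEC) and -0.18 (against control), the share nearer control was 84.6%, and the arginine and proline medians were -0.90 (NEC against control), 0.76 (PCI34051+NEC against NEC) and -0.23 (PCI34051+NEC against control). With a pseudocount of 0.25, genes set apart numbered 1167 for the control and 1180 for the PCI34051+NEC library, and the share nearer control was 85.1%. With a pseudocount of 4, which shrinks low genes, 2246 genes were higher in NEC than control, 2280 lower in PCI34051+NEC than NEC and 349 lower in PCI34051+NEC than control, 384 and 447 were set apart for control and PCI34051+NEC, and the share was 89.4%. Leaving out the filter could not change the counts or the share, since a gene below 1 CPM cannot reach 2-fold with a pseudocount of 1. With no filter the arginine and proline medians were -0.50 (NEC against control) and 0.59 (PCI34051+NEC against NEC). With a minimum of 5 CPM they were -0.97 and 1.03, and the share was 88.2%. With the GC content and length trend removed, the arginine and proline medians were -0.66 (NEC against control) and 0.99 (PCI34051+NEC against NEC). At 1.5-fold, by construction a looser limit, 2183 genes were higher and 2269 lower in PCI34051+NEC than control, and 2022, 8196 and 2362 were set apart for control, NEC and PCI34051+NEC. The cause of the other differences was not tested. Depth limits Hdac8, at 103 to 131 counts, more than Oat or Cps1.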

Other observations

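Some clock and immediate early genes were higher in both model libraries than in the control library that both comparisons share. Per1, a clock gene that glucocorticoids induce, was at 29.6, 260 and 180 CPM in the control, NEC and PCI34051+NEC libraries, and Nr1d1, a clock repressor, was at 5.22, 47.9 and 40.7 CPM. The 14 clock genes had medians of 0.06 in NEC and 0.43 in PCI34051+NEC against control, at percentiles 69.3 and 98.9, so that the list was within the random range in NEC. Immediate early genes had medians of 0.94 and 0.62, at percentiles 99.8 and 99.95, with Fos at 6.73, 32.5 and 70.9 CPM. Targets of hypoxia signalling had medians of -0.34 and 0.02, within the random range, although Ndrg1 was at 181, 408 and 1550 CPM. Genes of p53 and apoptosis were higher in PCI34051+NEC than control, with a median of 0.69 at percentile 99.97.

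Secretory cell genes went in different directions in the NEC library. Goblet cell genes had a median of 0.25 against control, with Fcgbp at 653 and 79.0 CPM and Spink4 at 6.48 and 37.4 CPM. Proliferation genes had a median of 0.10, with Mki67 at 25.4 and 78.9 CPM and Mcm6 at 57.5 and 15.8 CPM. The crypt base transcription factor Ascl2 was at 0.629, 17.8 and 1.05 CPM in the control, NEC and PCI34051+NEC libraries. Genes of the unfolded protein and integrated stress responses had a median of -0.98 in NEC and 0.03 in PCI34051+NEC against control. Of 60 lists with a percentile, 22 lay outside the central 95% of random lists in NEC against control. The numbers were 19 in PCI34051+NEC against NEC and 26 in PCI34051+NEC against control, and lists share genes.

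In the weighing that follows, the tests of depth, of 1 scaling factor, of muscle wall and of other cell types raised alike were chosen after the results were seen. The first pattern is that the NEC library stood apart, with 5331 genes set apart from both other libraries. Lower depth and GC content and length bias were argued against as whole causes, since 5307 and 5147 genes were still set apart with each removed, and so was 1 scaling factor on the NEC library, since no factor tried left fewer than 5307, where the larger count of the other libraries was 811, 747 and 766. Scaling without the mitochondrial and abundant genes left 5315, but it moved no library's size by more than 0.88% and so decided nothing. More muscle wall in the sample may account for part, with smooth muscle genes at a median of 1.498 and enteric neuron and glia genes at 2.05, but it would not by itself raise Paneth cell genes. The library's near-absence of Y-linked counts points to pups of another sex or another mixture of pups, and with 1 library the disease, the piece of intestine sampled, the litter and the handling of the sample all remain open. Proximal small intestine genes had medians of 0.66 (percentile 99.7) in PCI34051+NEC against control and 1.65 (99.6) against NEC. In NEC against control their median was -0.03 (61.0). The 4 colon genes measured had a median of -1.46 (2.22) in NEC against control and 1.70 (98.8) in PCI34051+NEC against NEC. Distal ileum genes were within the random range throughout. Whether the piece of intestine differed was not tested.

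The second pattern is the mitochondrially encoded share of 32.4% in the NEC library. More mitochondria or oxidative tissue predicted higher nuclear genes of oxidative phosphorylation. They were not higher, with a median of -0.79 and an upper bound of -0.68, which covers counting error only. Their percentile of 26.5 lay within the random range of -1.20 to 0.20, so they were not set apart from genes of like expression. Random lists were centred at -0.58, so a negative median was typical of such genes. The test found no rise, but it leaves this explanation open. RNA quality and the efficiency of messenger RNA selection could also alter this share, and neither was tested.

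The third pattern is the lower level of arginine and proline genes in the NEC library. A smaller epithelial share is a candidate explanation, although Paneth cell genes were higher, at 2.78. The list's median lay 0.53 above that of the junction genes, where a value below -0.48 would have argued against this explanation. That bound left out the centres of the matched random lists, -0.28 for the arginine and proline list and -0.68 for the junction list. The list also holds genes that were higher in the NEC library, such as Nos3, so the test could hardly have argued against the explanation. The urea cycle and citrulline list (-2.03) lay below the junction (-1.38) and absorptive enterocyte (-1.04) medians and above the suckling-type enterocyte median (-2.64). Whether the other cell types were raised alike stays open. Smooth muscle and macrophages lay 1.37 apart, within 1.80. That bound left out the centres of their matched random lists, -0.67 and 0.11, so the test decided nothing. The highest and lowest of 11 lists (enteric neurons and B cells) lay 4.28 apart against 3.01 for random lists. However, B cell genes were as low in PCI34051+NEC against control (-2.41), where the median of the arginine and proline list was near the control level. The comparison depends on the epithelial gene used: of 8 urea cycle and citrulline genes, 0 were lower than Epcam (-2.75), 5 lower than Cdh1 (-1.73) and 8 lower than Vil1 (-1.04) in log2 fold, a check made after the values were seen. Lower expression per enterocyte in NEC, and any effect of HDAC8 inhibition on it, therefore stay open and could not be separated from cell composition in these 3 libraries.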
